A study of Homo sapiens with 12 samples.

How the data were processed

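RNA from human foreskin fibroblasts (HFF2), primary connective-tissue cells of the skin, was measured on 12 Affymetrix oligonucleotide arrays, with 3 arrays in each of 4 groups. Per the labels, cells at 60% confluence formed the monolayer group. Cells were then kept in suspension over agarose, to which they cannot attach, and gathered into spheroids over 4 days in medium with 15% serum. The medium was taken off and the spheroids were stored for 2 weeks in the dark at room temperature, in flasks sealed under vacuum. Spheroids that received medium again formed the spheroid recovery group, and cells that had grown out as an attached layer for 7 days formed the monolayer recovery group. The labels do not say whether the spheroid group was collected before or after storage, nor how long after the return of medium the spheroid recovery group was collected. They call the samples triplicates, and nothing in them says that the 3 samples of a group came from separate cultures, so every p-value measures only the spread between these samples.

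The deposited table gave 1 intensity per probe set and array, on a linear scale in whole numbers from 4 to 12702, for 54675 probe sets with no missing value. How probes were summarised, how arrays were scaled and which software was used is not given in the sources used here. Array medians lay between 15 and 18, and the medians of the log2 values spanned 0.13. That was under the 0.2 set as the limit for quantile normalization, so no further normalization between arrays was applied. The medians are dim and close to the offset of 16 added before log2, so this limit says little about brighter probe sets. Upper quartiles ran from 43 on spheroid recovery array 1 to 56 on monolayer recovery array 3. Quantile normalization was therefore kept as an alternative. No detection calls were used, so whether a dim probe set was above background could not be assessed, and the number of arrays limits the precision.

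The 62 control probe sets were left out of the tests and were described separately. The 25% of the remaining 54613 probe sets with the lowest mean over all arrays (13654) were left out, and 40959 were tested. In the annotation of the array, 41097 probe sets named 1 gene, 1801 named several and 11777 named none. Genes were named only from probe sets with 1 gene, and 41043 of these matched a current symbol by gene number. Such probe sets made up 32137 of those tested and stood for 16888 genes. A gene with several probe sets was represented by the one with the highest mean over all arrays, and a change of another of its probe sets in the opposite direction is stated where the gene is described. Counts for a list are over its members with a tested probe set of their own.

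Each intensity was raised by 16 and log2-transformed, which understates the change of dim genes. A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation of the variance and two-sided moderated tests. Benjamini-Hochberg adjustment was made over all 40959 probe sets within each comparison, and an adjusted p under 0.05 counted as a change. The 5 comparisons were spheroid, spheroid recovery and monolayer recovery each against monolayer, spheroid recovery against spheroid, and monolayer recovery against spheroid recovery. Monolayer recovery against spheroid was tested in the same model only to count changes in spheroids that went back. An F test asked for any difference among the 4 groups. Changes are given on the log2 scale with the standard error (SE) of the model, and group levels as the mean ± SD of 3 deposited intensities. Sample names share only a number across groups, and no pairing was used.

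The genes named were chosen by a fixed rule. For each comparison with monolayer, it took the 10 largest rises and the 10 largest falls among changed genes whose 3 arrays of one group all lay above those of the other. It took 6 of each for the other comparisons. It added up to 4 changed genes per list with the largest changes, and 5 genes fixed by name (CIRBP, RBM3, ACTB, GAPDH and TBP). The 30 lists of genes, drawn up from general knowledge, were mitosis, DNA replication, p53 targets, quiescence and growth arrest, hypoxia response, glycolysis, cholesterol synthesis, ER stress, amino acid starvation response, heat shock, oxidative stress, collagen and matrix, matrix proteases and inhibitors, contractile and actin cytoskeleton, inflammatory cytokines, growth factors of clustered fibroblasts, interferon response, apoptosis machinery, autophagy and lysosome, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, immediate early genes, TGF-beta targets, integrins and cadherins, and markers of fibroblasts, keratinocytes, melanocytes, endothelial cells and leukocytes. Some genes stand in more than 1 list. Groups, comparisons, lists, the rule for named genes, filters, the tests of comparisons and lists, and every alternative but 1 were chosen before the data were examined. Some tests of explanations were chosen only after the result was seen, and these are named in the closing sections.

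Lists were tested with camera from limma, which compares the genes of a list with all other genes, at a preset correlation between genes of 0.01. Adjustment was made over the 150 tests of 30 lists in 5 comparisons. Each test was repeated with the correlation estimated from the data, and with fry, which asks whether the genes of a list moved on balance one way. Counts of changed list members are given as adjusted over all probe sets, with the count adjusted over the list alone beside it. A difference between the 4 groups in signals of the control probe sets was described without a test.

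The procedure was tested on simulated data of 40959 probe sets with the layout of the spheroid and monolayer arrays. It recovered 48 of 67 probe sets changed by 0.5 on the log2 scale, 63 of 67 changed by 1, and 66 of 66 changed by 2, and called 12 of 40759 unchanged probe sets. Alternatives covered quantile normalization, a shift of each array to a common median, no filter and a filter on the dimmest 50%, offsets of 1 and 64, a block for the number in the sample name, a variance trend, array weights, fits with the arrays of the compared groups alone, an adjusted p of 0.01, a 2-fold minimum, 1 probe set per gene, the mean over all probe sets of a gene, and leaving out each array in turn. Scaling each array to 5 bioB and bioC hybridization control probe sets was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.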

Results

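The study followed human foreskin fibroblasts from an attached monolayer into spheroids, and after storage through recovery in medium to a new monolayer. Its title names spheroid formation and recovery at ambient temperature as the subject. Each of the 4 groups had 3 arrays, and each array gave 54675 intensities with a median between 15 and 18. Across probe sets, which are not independent of each other, Pearson's r between arrays of 1 group lay between 0.988 and 0.997. Monolayer recovery arrays stood closest to monolayer arrays (r from 0.99 to 0.994). Between monolayer and spheroid arrays r lay from 0.936 to 0.951, and between monolayer and spheroid recovery arrays from 0.880 to 0.892. Of the 40959 probe sets tested, 23775 differed among the 4 groups.

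**Figure D1:**
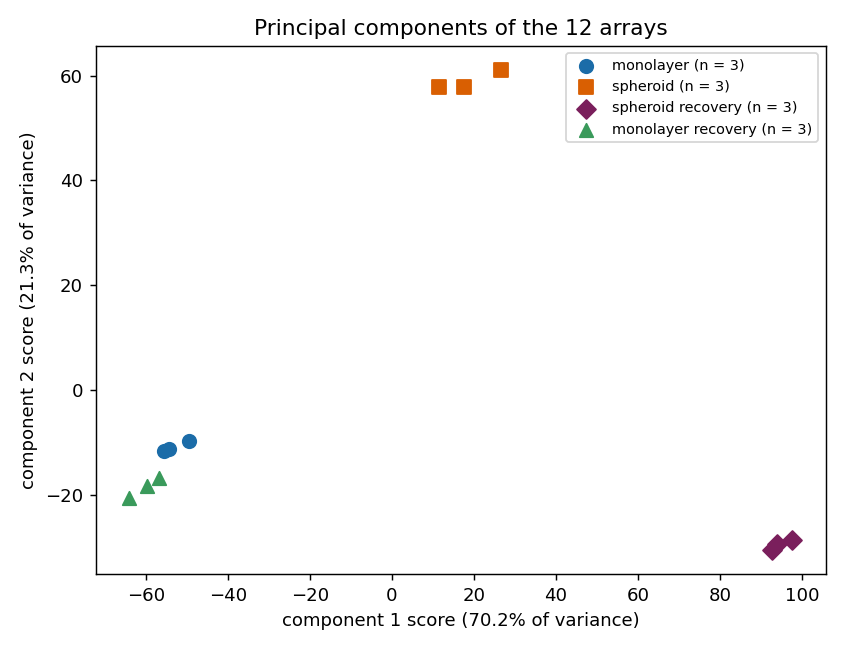
Each point is 1 of the 12 arrays, placed by its scores on principal components 1 and 2 of the log2 intensities, which carry 70.2% and 21.3% of the variance, and its marker gives its group. The 3 arrays of each group lie together, and monolayer and monolayer recovery arrays lie near each other.

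In spheroids, compared with the monolayer they were made from, genes of inflammatory signalling rose, and genes of cell division, DNA replication and the contractile cytoskeleton fell. IL24, a secreted cytokine, rose from an intensity of 17.7 ± 4.51 in monolayer to 3038 ± 194 in spheroids (mean ± SD, n = 3), a log2 change of 6.51 ± 0.095 (SE). CXCL1 and CXCL8, chemokines that attract neutrophils, rose from 53 ± 3 to 4807 ± 61 and from 76.7 ± 7.64 to 4083 ± 289. AURKA, a kinase of mitosis, fell from 961 ± 43.4 to 129 ± 13.1, and MYLK, the kinase that switches on smooth-muscle myosin, fell from 3268 ± 199 to 987 ± 48. The comparison addresses what the gathering of cells into spheroids changed, and it may hold storage too, since the labels do not place the spheroid samples before or after it. Loss of attachment and 4 days of culture came with gathering, and no serum level is given for the monolayer group. These cannot be told apart here.

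Of 28 measured inflammatory cytokine genes, 25 rose and 1 fell (25 and 1 adjusted over the list alone), with a median log2 change of 2.27 (camera adjusted p = 1.22e-22). CCL8, CXCL6 and CXCL2, further chemokines, rose by 5.68, 5.33 and 5.27 on the log2 scale. Growth factors of clustered fibroblasts followed, with 10 of 16 higher and 2 lower (10 and 3 adjusted over the list alone; median 0.47, adjusted p = 2.96e-05). Among them HGF, a growth factor for epithelial cells, rose from 22 ± 3.46 to 1403 ± 158, and STC1, a secreted glycoprotein, from 260 ± 28 to 5015 ± 297. Of 23 matrix proteases and inhibitors, 15 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.75, adjusted p = 1.31e-07, and adjusted p = 0.0504 with an estimated correlation). MMP3, which degrades matrix proteins, rose from 103 ± 10.5 to 2435 ± 73.4, and MMP1, a collagenase, from 1577 ± 66.4 to 7252 ± 199. Immediate early genes went both ways, with 9 of 21 higher and 6 lower in either count (median 0.16, adjusted p = 0.0297, and adjusted p = 0.292 with an estimated correlation). NR4A2, a nuclear receptor, rose by 4.10 on the log2 scale, while CCN1, a secreted matrix protein, fell by 1.77. Other genes among the largest rises were CHI3L1, IL13RA2 and CH25H, at 5.56, 5.47 and 5.32. On the spheroid arrays the ratio of the 3-prime to the 5-prime actin control signal was 136.5 ± 9.36, against 30.1 ± 2.03 in monolayer.

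Genes of proliferation fell together. In the mitosis list 34 of 35 genes fell (35 adjusted over the list alone; median −1.85, adjusted p = 7.92e-23). CCNB1, the cyclin of entry into mitosis, fell from 319 ± 21 to 36.3 ± 11.4, and BIRC5, or survivin, from 1490 ± 77.4 to 226 ± 38.7. In the DNA replication list 31 of 35 genes fell (33 adjusted over the list alone; median −0.83, adjusted p = 6.09e-14), among them TYMS, thymidylate synthase, from 881 ± 13.5 to 185 ± 7.23. Of 19 genes of quiescence and growth arrest, 11 rose and 5 fell (12 and 6 adjusted over the list alone; median 0.38, adjusted p = 0.0133, and adjusted p = 0.494 with an estimated correlation). CDKN2B, an inhibitor of cyclin-dependent kinases, rose from 164 ± 15.4 to 821 ± 44.6, and GAS6, a secreted ligand first found in growth-arrested cells, fell by 1.75 on the log2 scale. The 21 p53 targets were not called (adjusted p = 0.595), with 6 higher and 6 lower in either count; GADD45A fell by 1.60 and TP53INP1 rose by 0.97. These falls stood beside an intensity of the middle 28S rRNA control of 110.3 ± 11.5 in spheroids and 36.3 ± 3.06 in monolayer.

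Of 22 contractile and actin cytoskeleton genes, 21 fell in either count (median −0.88, adjusted p = 5.96e-13). TAGLN, an actin-binding protein of smooth muscle, fell by 3.44 on the log2 scale and TPM1, a tropomyosin, by 1.98. Collagen and matrix genes were not called (8 of 31 higher and 14 lower, 8 and 15 adjusted over the list alone; adjusted p = 0.0687, and 0.0328 without monolayer array 2). The collagen and matrix list passed as lower with the mean over all probe sets of a gene (camera adjusted p = 0.00599). LOX, which cross-links collagen, fell from 1299 ± 88.5 to 61.3 ± 6.81, and COL12A1 fell by 2.46. TGF-beta targets (6 of 16 higher and 2 lower, 7 and 2 adjusted over the list alone; adjusted p = 0.0589, and 0.0498 without monolayer array 1) and integrins and cadherins (3 of 18 higher and 5 lower, 4 and 6 adjusted over the list alone; adjusted p = 0.702) were not called either. ITGA4, an integrin subunit, fell by 2.77 and PMEPA1, a TGF-beta target, rose by 2.15. Fibroblast markers went both ways (6 of 15 higher and 6 lower in either count; adjusted p = 0.897), with THY1, a surface glycoprotein, lower at 257 ± 16.5 against 1461 ± 48.3 and PDGFRB, a PDGF receptor, higher by 1.22.

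Amino acid and sterol genes fell as groups. Of 24 genes that cells raise when amino acids run short, 19 fell and 1 rose (20 and 1 adjusted over the list alone; median −1.13, adjusted p = 2.92e-09). ASNS, asparagine synthetase, fell from 1104 ± 84.3 to 75.7 ± 17.6 and PSAT1, of serine synthesis, from 1055 ± 81.1 to 71 ± 14.4. Of 19 cholesterol synthesis genes, 14 fell (15 adjusted over the list alone; median −0.85, adjusted p = 1.66e-06), among them INSIG1, a sensor of sterol levels, from 1207 ± 90 to 388 ± 58.9. Glycolysis (1 of 17 higher and 11 lower, 2 and 12 adjusted over the list alone; median −0.26, adjusted p = 0.00875) lost its call with an estimated correlation (adjusted p = 0.217) and with scaling to the hybridization controls (adjusted p = 0.0621). Heat shock genes (1 of 17 higher and 9 lower in either count; median −0.26, adjusted p = 0.0235) did so too, at adjusted p = 0.201 with an estimated correlation and adjusted p = 0.0512 with that scaling. PKM, a pyruvate kinase, fell by 1.22 and HSPB1, a small heat shock protein, by 1.31. Hypoxia response genes were called as higher (14 of 26 higher and 6 lower in either count; median 0.24, adjusted p = 0.0398, adjusted p = 0.307 with an estimated correlation, and adjusted p = 0.0599 without spheroid array 2). MXI1 and ERO1A rose by 1.54 and 1.44, whereas SLC2A1, a glucose transporter that low oxygen raises, fell by 1.70. Autophagy and lysosome genes (10 of 27 higher and 3 lower in either count; median 0.08, adjusted p = 0.0261) lost the call at adjusted p = 0.478 with an estimated correlation and at adjusted p = 0.0541 without spheroid array 2; WIPI1 rose by 1.55.

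The remaining lists were not called in spheroids. ER stress genes had 4 of 24 higher and 4 lower (6 and 4 adjusted over the list alone; adjusted p = 0.308), with DNAJB9, a chaperone of the endoplasmic reticulum, higher by 2.33. Oxidative stress genes had 9 of 29 higher and 10 lower (10 and 11 adjusted over the list alone; adjusted p = 0.592), with SOD2 higher by 1.90 and SLC7A11, a cystine transporter, lower at a log2 change of −2.21. Interferon response genes had 3 of 23 higher and 8 lower (4 and 8 adjusted over the list alone; adjusted p = 0.319); IFIT2 and GBP1 fell by 2.23 and 2.13. Changed members numbered 9 of 21 for apoptosis machinery, 11 of 28 for oxidative phosphorylation, 2 of 25 for ribosomal proteins and 7 of 19 for ribosome biogenesis in either count (adjusted p = 0.606, 0.0554, 0.912 and 0.884). Oxidative phosphorylation passed without monolayer array 3 (0.0254), spheroid array 2 (0.0374) or spheroid recovery array 1 (0.0496). MITF of the melanocyte list fell by 1.84 and PECAM1 of the endothelial list rose by 1.38. Changed members numbered 3 of 11 keratinocyte, 3 of 6 melanocyte and 2 of 9 endothelial markers (3, 4 and 2 adjusted over the list alone; adjusted p = 0.941, 0.768 and 0.473). None of 9 leukocyte markers changed by limma in either count or at an unadjusted p under 0.05 (camera adjusted p = 0.459, fry adjusted p = 0.127). Median, mean and test did not share a sign for p53 targets, ER stress, ribosomal proteins, integrins and cadherins, fibroblast, keratinocyte and melanocyte markers. GAPDH and ACTB, often used as reference genes, fell by 0.60 and 0.29 and RBM3, a cold-induced RNA-binding protein, by 0.48. CIRBP, another, was at 0.12 (adjusted p = 0.097) and TBP at −0.029 (adjusted p = 0.843).

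In all, 13066 probe sets changed between spheroids and monolayer, 5251 higher and 7815 lower, standing for 2364 genes higher and 3929 lower. The balance depended on normalization: 6548 were higher and 6732 lower with quantile normalization, and 3903 and 8471 with a shift to a common median. Calls of 7 lists held with an estimated correlation, at adjusted p from 0.0102 to 0.0489: mitosis, DNA replication, inflammatory cytokines, contractile and actin cytoskeleton, amino acid starvation response, cholesterol synthesis and growth factors. Directions are relative to arrays with nearly equal medians. Scaled to the hybridization controls, an alternative chosen after seeing the data, the median of all probe sets moved to −0.51 and 37125 of 38198 changed probe sets were lower. List medians were then below 0 for growth factors of clustered fibroblasts (−0.057), quiescence and growth arrest (−0.15), hypoxia response (−0.29), immediate early genes (−0.37) and autophagy and lysosome (−0.45), each still above other genes in the list test, and the median for matrix proteases and inhibitors was 0.22. The list of TGF-beta targets passed with that scaling (adjusted p = 0.0138), with its median turned to −0.39.

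**Figure D2:**
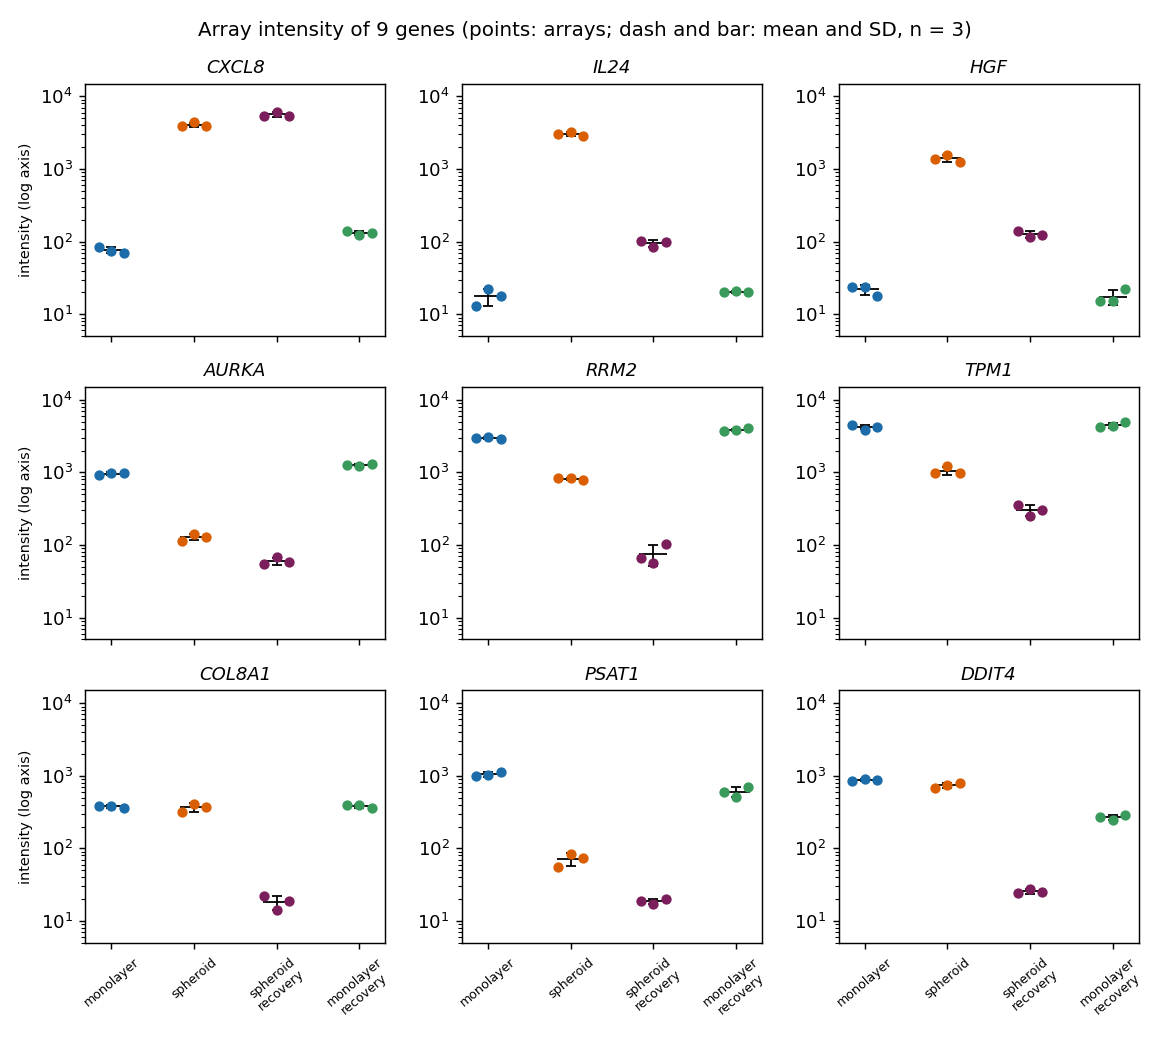
Deposited intensity on a log axis for 9 genes in the 4 groups, with points for the 3 arrays of each group and the mean ± SD. IL24 rises from 17.7 in monolayer to 3038 in spheroids, and AURKA falls from 961 to 129 and stands at 1262 in monolayer recovery.

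In spheroids returned to medium after storage, inflammatory cytokine genes stood above their monolayer level as a group, and contractile and collagen genes stood below it. CXCL2, a neutrophil chemokine, rose from 17.7 ± 2.08 in monolayer to 3823 ± 334 in spheroid recovery (mean ± SD, n = 3), a log2 change of 6.83 ± 0.102 (SE). CXCL8 stood at 5658 ± 464, against 76.7 ± 7.64. RRM2, a subunit of ribonucleotide reductase, fell from 2961 ± 105 to 75 ± 23.8, and THY1 fell from 1461 ± 48.3 to 73.7 ± 4.93. The comparison addresses how stored spheroids back in medium differed from the cells before gathering.

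Of the 28 inflammatory cytokine genes, 19 rose and 2 fell (20 and 2 adjusted over the list alone; median 1.13, adjusted p = 2.12e-07), and the median was 0.47 with scaling to the hybridization controls. Growth factors had 8 of 16 higher and 3 lower (9 and 4 adjusted over the list alone; median 0.23, adjusted p = 0.0235). That call ended with an estimated correlation (adjusted p = 0.194) and with the mean over all probe sets of a gene (adjusted p = 0.0802), and the median was −0.44 with scaling to the hybridization controls. EREG, a ligand of the EGF receptor, rose from 399 ± 11 to 4070 ± 245, and BMP2, a bone morphogenetic protein, by 2.97 on the log2 scale. Matrix proteases (10 of 23 higher and 5 lower in either count; adjusted p = 0.0687, and 0.0492 without spheroid recovery array 2) and immediate early genes (10 of 21 higher and 5 lower in either count; adjusted p = 0.148) were not called. MMP3 rose by 3.55 and IER3, an early response gene, by 3.21, while ADAM12, a membrane protease, fell by 2.23. UPP1, uridine phosphorylase, rose from 43 ± 7.21 to 996 ± 41.8, and IL13RA2 rose by 4.21. On these arrays the actin control ratio was 193 ± 36.2, against 30.1 ± 2.03 in monolayer, and the 5-prime 28S rRNA control signal was 108 ± 21.7, against 10.3 ± 0.577.

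Of the 35 mitosis genes, 34 fell (35 adjusted over the list alone; median −1.90, adjusted p = 1.26e-15, and adjusted p = 0.0504 with an estimated correlation). AURKA fell from 961 ± 43.4 to 60.3 ± 6.81 and KIF11, a motor of the spindle, from 818 ± 2.08 to 49.7 ± 2.31. Of the 35 DNA replication genes, 29 fell in either count (median −0.78, adjusted p = 5.83e-08, and adjusted p = 0.0633 with an estimated correlation). UHRF1 and PCNA, the sliding clamp of DNA polymerase, fell by 3.52 and 2.38. Quiescence genes (7 of 19 higher and 8 lower in either count; adjusted p = 0.975) and p53 targets (6 of 21 higher and 10 lower, 6 and 11 adjusted over the list alone; adjusted p = 0.461) were not called. BAX, a promoter of cell death, fell from 109 ± 12.7 to 17 ± 2.65, and TP53INP1 rose by 1.61.

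Of the 22 contractile genes, 21 fell in either count (median −1.51, adjusted p = 1.08e-09), with TPM1 down from 4207 ± 295 to 303 ± 51.1. Collagen and matrix genes fell as well, 22 of 31 against 2 higher in either count (median −1.01, adjusted p = 1.78e-07), among them COL8A1 from 379 ± 13.9 to 18.3 ± 4.04. Fibroblast markers had 2 of 15 higher and 10 lower (2 and 11 adjusted over the list alone; median −0.81, adjusted p = 0.00492). The call ended with an estimated correlation (adjusted p = 0.0554) and with scaling to the hybridization controls (adjusted p = 0.122). S100A4 fell by 2.47, while PRRX1, a transcription factor of connective tissue, rose by 2.01 with 1 of its 3 probe sets lower. Integrins and cadherins (3 of 18 higher and 11 lower in either count; adjusted p = 0.0758) and TGF-beta targets (3 of 16 higher and 8 lower in either count; adjusted p = 0.368) were not called. Integrins and cadherins did pass with the mean over all probe sets of a gene (camera adjusted p = 0.0468, median −0.24). ITGA4 fell by 3.54 and SMAD7, an inhibitor of TGF-beta signalling, rose by 1.73. The GAPDH control ratio of 3-prime to 5-prime signal was 2.99 ± 0.219 on these arrays and 2.37 ± 0.0963 on monolayer arrays.

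Of 17 glycolysis genes, 15 fell and 2 rose in either count (median −1.18, adjusted p = 7.83e-05, and adjusted p = 0.0856 with an estimated correlation); TPI1 and GPI, enzymes of the pathway, fell by 1.69 and 1.59. Amino acid starvation genes had 18 of 24 lower and 2 higher in either count (median −0.87, adjusted p = 1.21e-05, and adjusted p = 0.111 with an estimated correlation), and PSPH, of serine synthesis, fell by 4.48. Oxidative phosphorylation genes had 20 of 28 lower and 1 higher in either count (median −0.53, adjusted p = 0.000107, and adjusted p = 0.382 with an estimated correlation). NDUFB5, a subunit of respiratory complex I, fell from 629 ± 17.6 to 67.3 ± 7.77. Heat shock genes had 11 of 17 lower and 1 higher in either count (median −0.32, adjusted p = 0.00891, and adjusted p = 0.14 with an estimated correlation), with HSPB1 lower at a log2 change of −2.75. Cholesterol synthesis genes (1 of 19 higher and 11 lower, 2 and 11 adjusted over the list alone; adjusted p = 0.0524, and 0.0395, 0.0447 and 0.0464 without monolayer, spheroid recovery and monolayer recovery array 3) and oxidative stress genes (8 of 29 higher and 15 lower in either count; adjusted p = 0.174) were not called. Cholesterol synthesis genes did pass with the mean over all probe sets of a gene (camera adjusted p = 0.038, median −0.23). NQO1, a quinone reductase, fell from 1589 ± 56 to 70.7 ± 26.4.

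Hypoxia response genes (14 of 26 higher and 8 lower in either count; adjusted p = 0.145), ER stress genes (10 of 24 higher and 12 lower in either count; adjusted p = 0.872) and autophagy genes (13 of 27 higher and 6 lower, 14 and 7 adjusted over the list alone; adjusted p = 0.0634, and 0.0438 without monolayer array 2) were not called. DDIT4, an inhibitor of mTOR signalling, fell from 877 ± 30.5 to 25.7 ± 2.08, KDM3A, a histone demethylase, rose by 2.38, and MAP1LC3B, of autophagosomes, rose by 1.17. Neither were interferon response (4 of 23 higher and 8 lower in either count; adjusted p = 0.23), apoptosis machinery (7 of 21 higher and 5 lower, 7 and 6 adjusted over the list alone; adjusted p = 0.905), ribosomal proteins (5 of 25 higher and 10 lower, 6 and 10 adjusted over the list alone; adjusted p = 0.606) or ribosome biogenesis (6 of 19 higher and 11 lower, 6 and 12 adjusted over the list alone; adjusted p = 0.684). Changed members numbered 3 of 11 keratinocyte, 4 of 6 melanocyte, 3 of 9 endothelial and 1 of 9 leukocyte markers in either count (adjusted p = 0.913, 0.514, 0.711 and 0.274). Autophagy genes passed as higher with quantile normalization (camera adjusted p = 0.0129) and with a shift to a common median (0.0471). Median, mean and test did not share a sign for quiescence, apoptosis machinery and keratinocyte markers. GAPDH fell by 1.21 and ACTB by 0.47, and RBM3 was at 0.09 (adjusted p = 0.362) and at −0.57 with scaling to the hybridization controls. TBP, at −0.25 (adjusted p = 0.0277), turned to 0.12 with quantile normalization and lost its call without monolayer array 1, 2 or 3 or spheroid recovery array 2 or 3 (adjusted p up to 0.105). CIRBP, at 0.66, had 3 of 5 probe sets that moved the opposite way and lay at −0.004 with scaling to the hybridization controls.

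Between spheroid recovery and monolayer, 21025 probe sets changed, 11013 higher and 10012 lower, standing for 4323 genes higher and 5089 lower. Calls of 3 lists held with an estimated correlation, contractile, inflammatory and collagen genes, at adjusted p from 0.0152 to 0.0399. Of 8252 genes with several probe sets, 78 had probe sets changed at least 2-fold in opposite directions. With a shift to a common median 8748 probe sets were higher and 10729 lower, and with a 2-fold minimum 1561 were higher and 3753 lower. With scaling to the hybridization controls the median of all probe sets moved to −0.61, and 36128 of 38103 changed probe sets were lower. Hypoxia response, matrix proteases and inhibitors, autophagy and lysosome, and immediate early genes then passed as higher than other genes (adjusted p = 2e-04, 0.000695, 0.017 and 0.00835), with medians turned to −0.39, −0.57, −0.37 and −0.43.

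**Figure D3:**
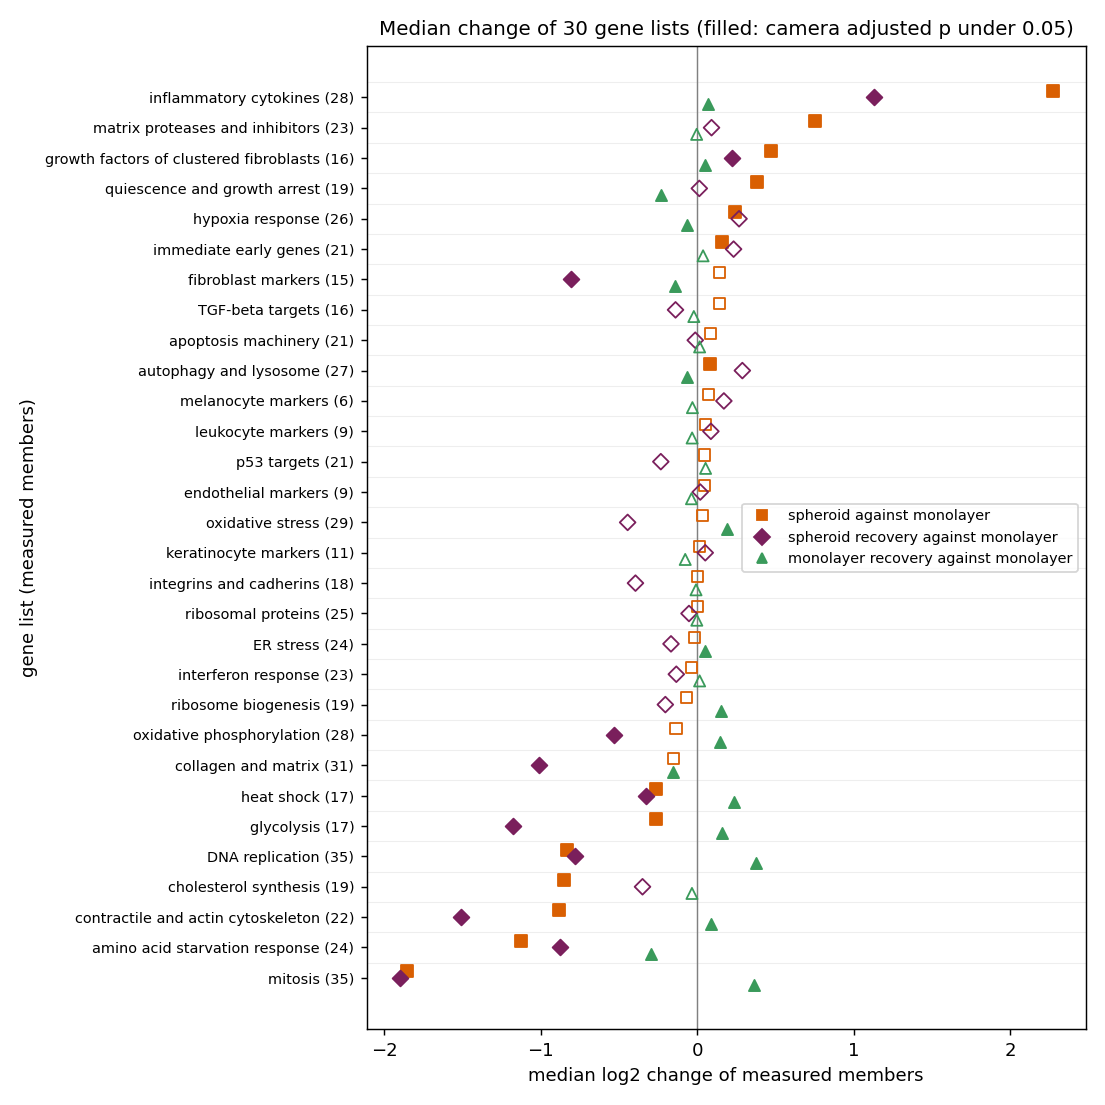
Median log2 change of each of the 30 gene lists in the 3 comparisons with monolayer, with filled markers for lists past the threshold of the camera test. The inflammatory list lies at 2.27 in spheroids and 1.13 in spheroid recovery, and the mitosis list at −1.85 and −1.90.

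Of the 13066 probe sets changed in spheroids, 9459 changed the same way in spheroid recovery and 1379 the opposite way. For those higher in spheroids, 3510 of 5251 were higher in spheroid recovery too, where independence would give 1412. For those lower, the number was 5949 of 7815, where independence would give 1910. Across probe sets, which are not independent, both changes had r = 0.625 and a covariance of 0.23. Both comparisons share the monolayer arrays, which alone gave a simulated r of 0.5, a covariance of 0.00478 and 0.05 shared calls per simulation. The simulated covariance lay far below the observed 0.23, which argues against the shared arrays as the main source of the excess. Both groups also differed from monolayer in control probe sets, with actin control ratios of 136.5 and 193 against 30.1. How much of the shared changes goes with that difference was not tested. The simulated r came from probe sets without any change, so it is no measure for the observed r.

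Compared with spheroids, spheroid recovery had lower levels of collagen and matrix genes and of fibroblast markers. CCL8 fell from 1574 ± 151 in spheroids to 16.3 ± 2.08 in spheroid recovery (mean ± SD, n = 3), a log2 change of −5.62 ± 0.08 (SE). CCL2, which attracts monocytes, fell from 1635 ± 46.9 to 176 ± 17.7, and PDGFRA, a PDGF receptor, from 4488 ± 167 to 1200 ± 72.5. UPP1 rose from 46.7 ± 7.51 to 996 ± 41.8, and ADM, the vasodilator adrenomedullin, from 1305 ± 48.2 to 5753 ± 579. The comparison addresses what changed on the way from the spheroid to the recovery sample. The return of medium lay between them, and the labels do not say whether storage did too.

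Of 28 inflammatory cytokine genes, 17 fell and 4 rose (17 and 7 adjusted over the list alone; median −0.44, adjusted p = 0.000533, and adjusted p = 0.109 with an estimated correlation). IL24 fell by 4.78 on the log2 scale and CCL7 by 3.67. Collagen and matrix genes had 23 of 31 lower and 2 higher (25 and 2 adjusted over the list alone; median −0.60, adjusted p = 1.88e-07), with COL4A1, a basement membrane collagen, down from 1653 ± 76.4 to 382 ± 12.1. Fibroblast markers had 12 of 15 lower and 1 higher in either count (median −0.93, adjusted p = 7.74e-05). These were the 2 calls that held with an estimated correlation, at adjusted p = 0.0399 and 0.0322. Contractile genes (12 of 22 lower and 2 higher in either count; median −0.27, adjusted p = 0.00505) and matrix proteases (12 of 23 lower and 2 higher in either count; median −0.24, adjusted p = 0.00404) had adjusted p = 0.0977 and 0.225 with an estimated correlation. ADAM12 fell by 3.58 and TIMP1, an inhibitor of matrix proteases, by 1.15. TGF-beta targets had 9 of 16 lower and 2 higher in either count (median −0.45, adjusted p = 0.0295, and adjusted p = 0.14 with an estimated correlation), with SNAI2, a transcription factor, down by 2.45. The 5-prime 28S rRNA control signal was 108 ± 21.7 in spheroid recovery and 15.3 ± 0.577 in spheroids.

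Glycolysis (12 of 17 lower and 3 higher in either count; median −0.66, adjusted p = 0.00111) and oxidative phosphorylation (15 of 28 lower in either count; median −0.18, adjusted p = 0.00146) had adjusted p = 0.14 and 0.474 with an estimated correlation. TPI1 fell by 1.49 and NDUFB5 by 2.89, while HK2, a hexokinase, rose by 1.07. Oxidative stress genes (17 of 29 lower and 5 higher in either count; median −0.55, adjusted p = 0.00747) and quiescence genes (12 of 19 lower and 3 higher, 12 and 4 adjusted over the list alone; median −0.79, adjusted p = 0.00874) had adjusted p = 0.489 and 0.478 with an estimated correlation. NQO1 fell from 1210 ± 39.7 to 70.7 ± 26.4, CDKN2B fell by 2.32, and TXNIP, a brake on glucose uptake, rose by 1.51. Mitosis genes fell further in 12 of 35 cases and rose in 2 (either count; median −0.11, adjusted p = 0.0452). The call ended with an estimated correlation (adjusted p = 0.579), with the mean over all probe sets (adjusted p = 0.0768), with scaling to the hybridization controls (adjusted p = 0.0514), and without spheroid array 2 (0.0851), spheroid array 3 (0.0656) or spheroid recovery array 2 (0.0728). CDK1, the kinase of mitotic entry, fell from 103 ± 9.54 to 24.3 ± 1.53. Among lists not called, cholesterol synthesis had 7 of 19 higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p = 0.0736), with HMGCS1 and SQLE, enzymes of the pathway, higher by 1.71 and 1.42. With the mean over all probe sets of a gene, the lists of ER stress and of integrins and cadherins passed here. Their camera adjusted p was 0.0429 and 0.0468, with medians of −0.26 and −0.13. Median, mean and test did not share a sign for DNA replication, hypoxia response, autophagy, ribosome biogenesis and immediate early genes.

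Spheroid recovery and spheroid arrays differed in 13947 probe sets, 6877 higher and 7070 lower, standing for 2938 genes higher and 3858 lower. With quantile normalization 8117 were higher and 7007 lower. Scaling to the hybridization controls moved the median of all probe sets to −0.11 and gave 4237 higher and 9318 lower, and cholesterol synthesis then passed (adjusted p = 0.0203). Among genes with several probe sets, 67 of 8252 had probe sets changed at least 2-fold in opposite directions.

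After 7 days of attached growth, the recovered monolayer carried more RNA of replication and mitosis genes than the starting monolayer, and less of genes for matrix and the amino acid starvation response. MCM5, of the replicative helicase, rose from 26.7 ± 3.06 to 58.3 ± 11 (mean ± SD, n = 3), a log2 change of 0.79 ± 0.09 (SE), and CDC20, an activator of the anaphase-promoting complex, from 52 ± 8.54 to 87 ± 6.93. DCN, the matrix proteoglycan decorin, fell from 1640 ± 154 to 821 ± 96.4. DDIT4 fell from 877 ± 30.5 to 267 ± 21.1 (adjusted p = 7.08e-07). The comparison addresses how far cells that had grown out again resembled those they came from.

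Mitosis genes had 13 of 35 higher (23 adjusted over the list alone; median 0.37, adjusted p = 1.95e-18), and DNA replication genes 14 of 35 (28 adjusted over the list alone; median 0.38, adjusted p = 2.26e-20). Quiescence genes had 7 of 19 lower (10 adjusted over the list alone; median −0.23, adjusted p = 4.04e-10, and adjusted p = 0.109 with an estimated correlation), with KLF9, a transcription factor, down by 0.80 and TXNIP by 1.23 on the log2 scale. Of 24 amino acid starvation genes, 9 fell (12 adjusted over the list alone; median −0.30, adjusted p = 5.74e-11), ASNS from 1104 ± 84.3 to 570 ± 19.1. Hypoxia response genes had 6 of 26 lower (7 lower and 1 higher adjusted over the list alone; median −0.062, adjusted p = 0.000201, and adjusted p = 0.0923 with an estimated correlation), and VEGFA, a growth factor for blood vessels, fell by 0.80. Collagen and matrix genes had 8 of 31 lower (15 adjusted over the list alone; median −0.16, adjusted p = 9.07e-10), POSTN, or periostin, from 2339 ± 140 to 1401 ± 120. Fibroblast markers had 3 of 15 lower (6 adjusted over the list alone; median −0.14, adjusted p = 9.87e-06), with PDGFRA down by 0.55. Glycolysis genes had 3 of 17 higher (7 adjusted over the list alone; median 0.16, adjusted p = 1.24e-05, and adjusted p = 0.0633 with an estimated correlation), with PFKP, a phosphofructokinase, up by 0.50. Heat shock genes had 3 of 17 higher (8 adjusted over the list alone; median 0.24, adjusted p = 8.18e-07), with HSPA4 up by 0.39.

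A few inflammatory and growth factor genes stood slightly higher in the recovered monolayer. CXCL1 rose from 53 ± 3 to 117 ± 11.8 and EREG from 399 ± 11 to 852 ± 90, and MMP3 rose by 0.85. Inflammatory cytokine genes had 6 of 28 higher and 3 lower (9 and 4 adjusted over the list alone; median 0.07, adjusted p = 0.0295). The call ended with an estimated correlation (adjusted p = 0.292), with the mean over all probe sets (0.072), with a shift to a common median (0.0505), and without monolayer array 1 (0.0515) or monolayer recovery array 1 (0.056). CXCL12, a chemokine of stromal cells, fell by 0.88. Growth factors had 5 of 16 higher and 1 lower in either count (median 0.052, adjusted p = 0.032, adjusted p = 0.208 with an estimated correlation, and 0.0687 without monolayer recovery array 2). Contractile genes had 1 of 22 higher in either count (median 0.09, adjusted p = 0.00733, and adjusted p = 0.109 with an estimated correlation). Oxidative phosphorylation genes had 1 of 28 higher (7 adjusted over the list alone; median 0.15, adjusted p = 5.09e-06), oxidative stress genes 6 of 29 higher and 1 lower (9 and 1 adjusted over the list alone; median 0.19, adjusted p = 0.00146) and ribosome biogenesis genes 1 of 19 higher and 2 lower (9 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.0102). With an estimated correlation these had adjusted p = 0.292, 0.437 and 0.201. CYC1, of respiratory complex III, rose by 0.36 and SOD2 fell by 0.40.

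ER stress genes (5 of 24 higher, 7 higher and 1 lower adjusted over the list alone; median 0.052, adjusted p = 0.0499, and adjusted p = 0.307 with an estimated correlation) included HYOU1, a chaperone, and MANF, higher by 0.47 and 0.53. The call ended with quantile normalization (adjusted p = 0.204), with a replicate block (0.0548), with scaling to the hybridization controls (0.0587), and without monolayer array 1 (0.0519) or 2 (0.0713), spheroid array 1 (0.0648) or 2 (0.075), spheroid recovery array 1 (0.0538), or monolayer recovery array 1 (0.1) or 3 (0.0946). Autophagy genes (2 of 27 lower, 5 lower and 1 higher adjusted over the list alone; median −0.063, adjusted p = 0.044, and adjusted p = 0.504 with an estimated correlation) lost the call with scaling to the hybridization controls (0.0621), and without monolayer array 1 (0.0531) or 2 (0.161) or monolayer recovery array 1 (0.0596) or 2 (0.169). PSAP, a precursor of lysosomal activators, fell by 0.44. Not called were matrix proteases (5 of 23 higher and 2 lower, 6 and 4 adjusted over the list alone; adjusted p = 0.746), p53 targets (1 of 21 lower, 2 higher and 2 lower adjusted over the list alone; adjusted p = 0.606) and immediate early genes (3 of 21 higher, 4 adjusted over the list alone; adjusted p = 0.151). Nor were TGF-beta targets (1 of 16 higher and 1 lower in either count; adjusted p = 0.595), apoptosis machinery (1 of 21 higher in either count; adjusted p = 0.789) and keratinocyte markers (1 of 11 lower, 2 adjusted over the list alone; adjusted p = 0.11). By limma 0 members passed for cholesterol synthesis, interferon response, ribosomal proteins, integrins and cadherins, and melanocyte, endothelial and leukocyte markers. At an unadjusted p under 0.05 they had 4 of 19, 3 of 23, 3 of 25, 3 of 18, 0 of 6, 2 of 9 and 0 of 9 members, and fry gave adjusted p from 0.178 to 0.891. Median, mean and test did not share a sign for matrix proteases, interferon response, and integrins and cadherins. TGFBI, of the TGF-beta list, fell by 0.89. GAPDH, ACTB, TBP, CIRBP and RBM3 did not pass (adjusted p from 0.124 to 1).

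Monolayer recovery and monolayer arrays differed in 1321 probe sets, 690 higher and 631 lower, standing for 416 genes higher and 369 lower. With quantile normalization 799 were higher and 969 lower, and with a shift to a common median 665 and 462. Calls of 6 lists held with an estimated correlation, at adjusted p from 0.0185 to 0.0399: DNA replication, fibroblast markers, collagen and matrix, heat shock, mitosis and amino acid starvation response. Of 78 named genes called here, 26 lost the call on leaving out at least 1 array, against 4 of 126 for spheroid against monolayer. Among the 26 were TTK, BUB1 and CCNB1 of the mitosis list and CDC6, GINS1 and CCNE2 of the DNA replication list. Without monolayer array 1, 2 and 3 the count of probe sets was 701, 702 and 710, of which 353, 323 and 227 were higher. Without monolayer recovery array 1, 2 and 3 it was 745, 846 and 814, of which 365, 425 and 288 were higher. It was 689 with an offset of 1, of which 288 were higher, and 2514 with array weights. The actin control ratio was 25 ± 1.55 on monolayer recovery arrays, against 30.1 ± 2.03 in monolayer.

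Of the 13066 probe sets changed in spheroids, 11847 changed back between spheroids and monolayer recovery. The actin control ratio also went from 136.5 in spheroids to 25 in monolayer recovery, and its part in these 11847 changes was not tested. Compared with the starting monolayer, 294 of the 13066 were changed the same way in monolayer recovery and 790 the opposite way. Of the 5251 higher in spheroids, 97 stayed higher, where independence would give 88.5, and of the 7815 lower, 197 stayed lower, where independence would give 120.4. The opposite way went 357 and 433, where independence would give 80.9 and 131.7. Across probe sets, which are not independent, the changes in spheroids and in monolayer recovery had r = −0.175 and a covariance of −0.0133. The shared monolayer arrays alone gave a simulated r of 0.498, a covariance of 0.00475 and 0 shared calls, which pushes both changes the same way and not the opposite way. Those not called in monolayer recovery made up 91.4% and 91.9%, and the absence of a call does not show equal levels. The number 294 was 165 with an offset of 1, 171 and 164 without monolayer array 1 and 2, and 176 and 188 without monolayer recovery array 1 and 2.

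From spheroid recovery to monolayer recovery, genes of mitosis, DNA replication and contraction rose as groups, and inflammatory cytokine genes fell. RRM2 rose from 75 ± 23.8 to 3844 ± 175 (mean ± SD, n = 3), a log2 change of 5.44 ± 0.131 (SE). AURKA rose from 60.3 ± 6.81 to 1262 ± 30, and TPM1 from 303 ± 51.1 to 4481 ± 379. CXCL2 fell from 3823 ± 334 to 22.7 ± 5.51, and CXCL8 from 5658 ± 464 to 132 ± 8.19. The comparison addresses what changed as cells left the spheroids and grew attached.

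All 35 mitosis genes rose in either count (median 2.19, adjusted p = 9.78e-17), and 34 of 35 DNA replication genes (median 1.35, adjusted p = 3.53e-11), with PCNA up by 2.92. Contractile genes had 20 of 22 higher in either count (median 1.63, adjusted p = 6.96e-10). Collagen and matrix genes had 20 of 31 higher and 4 lower in either count (median 0.79, adjusted p = 0.000147, and adjusted p = 0.0856 with an estimated correlation), with COL8A1 up from 18.3 ± 4.04 to 384 ± 17.9. Between these groups the actin control ratio went from 193 ± 36.2 to 25 ± 1.55. Glycolysis genes had 14 of 17 higher and 1 lower (15 and 1 adjusted over the list alone; median 1.39, adjusted p = 2.93e-05), and oxidative phosphorylation genes 21 of 28 higher and 1 lower (22 and 1 adjusted over the list alone; median 0.75, adjusted p = 4.15e-06). With an estimated correlation they had adjusted p = 0.0714 and 0.292. Heat shock genes had 12 of 17 higher and 1 lower (13 and 1 adjusted over the list alone; median 0.59, adjusted p = 0.000766), and amino acid starvation genes 15 of 24 higher and 4 lower in either count (median 0.75, adjusted p = 0.00143). With an estimated correlation they had adjusted p = 0.0714 and 0.225. NDUFB5 rose by 2.96, HSPB1 by 3.03 and PSAT1 by 4.14 on the log2 scale.

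Inflammatory cytokine genes had 19 of 28 lower and 2 higher in either count (median −0.86, adjusted p = 5.61e-07), and the median was −0.18 with scaling to the hybridization controls. The 5-prime 28S rRNA control signal was 10.3 ± 0.577 in monolayer recovery, against 108 ± 21.7 in spheroid recovery. Autophagy genes had 16 of 27 lower and 6 higher in either count (median −0.38, adjusted p = 0.0212, and adjusted p = 0.474 with an estimated correlation), with MAP1LC3B down by 1.27; the median was 0.30 with scaling to the hybridization controls. Matrix proteases had 12 of 23 lower and 6 higher in either count (median −0.22, adjusted p = 0.0499, and adjusted p = 0.421 with an estimated correlation), with MMP3 down by 2.71; the median was 0.47 with that scaling. The protease call ended with the mean over all probe sets (adjusted p = 0.102), with a replicate block (0.0557), and without monolayer array 2 (0.05), spheroid array 1 (0.0638), 2 (0.0569) or 3 (0.0516), spheroid recovery array 1 (0.072), or monolayer recovery array 1 (0.0505) or 2 (0.0582). Among lists not called, fibroblast markers had 9 of 15 higher and 3 lower in either count (adjusted p = 0.0779), with THY1 up from 73.7 ± 4.93 to 1382 ± 35.9. Growth factors of clustered fibroblasts had 4 of 16 higher and 8 lower in either count (adjusted p = 0.0505), and passed without any 1 array other than monolayer array 1 and spheroid recovery array 3 (adjusted p from 0.0337 to 0.0496); with scaling to the hybridization controls they passed (adjusted p = 2.75e-06) and the median of −0.23 turned to 0.45. STC1 fell from 4203 ± 103 to 338 ± 5.29. Oxidative stress genes had 16 of 29 higher and 7 lower in either count (adjusted p = 0.0505), and passed without spheroid array 3 (0.0445), spheroid recovery array 1 (0.0374) or 3 (0.0383) or monolayer recovery array 3 (0.049). With the mean over all probe sets of a gene, the lists of oxidative stress and of integrins and cadherins passed. Their camera adjusted p was 0.0199 and 0.0328, with medians of 0.374 and 0.367. Median, mean and test did not share a sign for apoptosis machinery. GAPDH rose by 1.42.

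Monolayer recovery and spheroid recovery arrays differed in 23046 probe sets, 10692 higher and 12354 lower, standing for 5363 genes higher and 4861 lower. Mitosis, DNA replication, contractile and inflammatory lists held their calls with an estimated correlation, at adjusted p from 0.0152 to 0.0475. With scaling to the hybridization controls the median of all probe sets moved to 0.62 and 36077 of 38103 changed probe sets were higher, and with a shift to a common median 12158 were higher and 8440 lower. Scaled to the hybridization controls, quiescence and growth arrest, hypoxia response and immediate early genes passed as lower than other genes (adjusted p = 0.00761, 2.48e-05 and 0.0418), with medians turned to 0.55, 0.49 and 0.62.

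**Figure D4:**
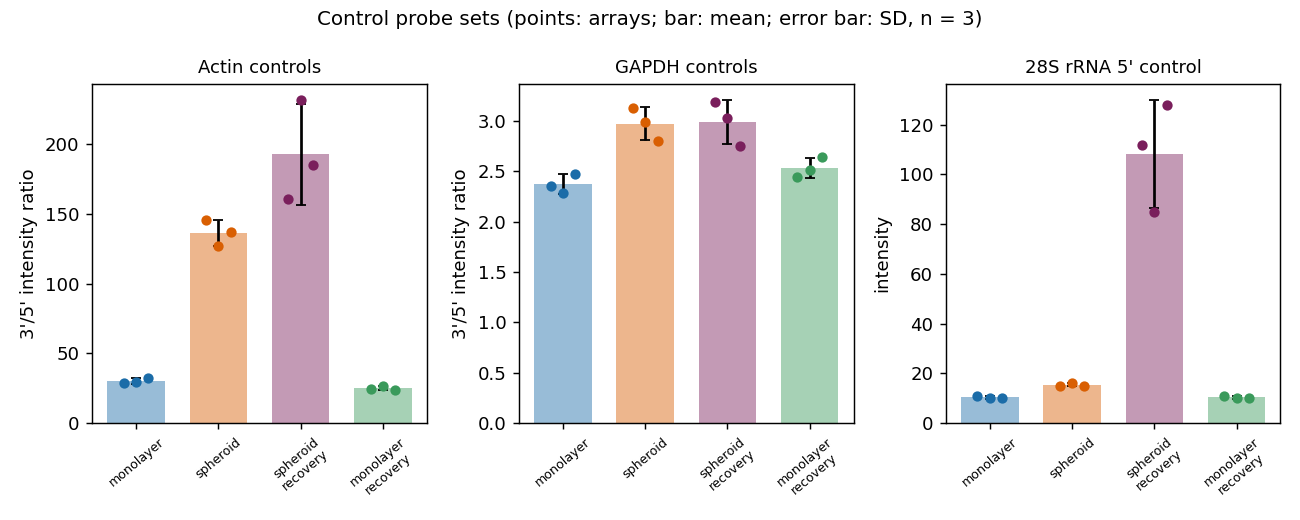
Mean ± SD over the 3 arrays of each group for signals of control probe sets, on axes that start at 0: ratios of 3-prime to 5-prime signal for actin and GAPDH, and the intensity of the 5-prime 28S rRNA control. The actin ratio is 30.1 in monolayer, 136.5 in spheroids and 193 in spheroid recovery.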

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

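Tests of the mitosis and inflammatory lists, of leukocyte markers and of probe sets bright on arrays outside the comparison were chosen only after the result was seen, whereas the splits of the arrays and the other tests of opposite probe sets were chosen before. Of the readings of control probe sets given here, which stand outside the comparisons of genes, all but the cre control were higher on every spheroid and spheroid recovery array than on the highest monolayer array. The ratio of 3-prime to 5-prime actin signal was 136.5 ± 9.36 (mean ± SD, n = 3) in spheroids and 193 ± 36.2 in spheroid recovery, against 30.1 ± 2.03 in monolayer. For GAPDH the ratios were 2.98 ± 0.165 and 2.99 ± 0.219, against 2.37 ± 0.0963. The bioB hybridization control read 1000 ± 40.9 and 1115 ± 46.1, against 700 ± 38.7, whereas the cre hybridization control, at 12537 ± 156 and 12097 ± 408 against 11948 ± 719, did not part the groups. The cre control was the highest reading of every array, and whether so high a signal could show a shift was not tested. The 5-prime 28S rRNA control read 15.3 ± 0.577 and 108 ± 21.7, against 10.3 ± 0.577, and the middle 28S rRNA control 110.3 ± 11.5 and 175 ± 12.7, against 36.3 ± 3.06. The Alu control read 9984 ± 73.6 and 10376 ± 93, against 9061 ± 224.

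The number of probe sets that differed among the 4 groups, 23775, was reached by 1 of 100 splits of the 12 arrays into groups of 3, the real one. The highest other split gave 8497, which argues against a random grouping of these arrays as its source. The splits cannot address differences between cultures, since nothing in the labels says that the 3 samples of a group came from separate cultures. For each comparison of 2 groups 1 of 10 splits, the real one, gave as many probe sets, and 10 splits are too few for a share under 0.05. The real counts were 13066 for spheroid against monolayer, 21025 for spheroid recovery against monolayer, 1321 for monolayer recovery against monolayer, 13947 for spheroid recovery against spheroid and 23046 for monolayer recovery against spheroid recovery. The highest other split gave 0 in each.

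Inflammatory cytokine genes stood higher in spheroids than in monolayer. If loss of signal from the 5-prime end of transcripts were the whole cause, the list was taken to move like other genes of the same level. Its median of 2.27 lay at percentile 100 of 10000 random lists matched on mean level, whose middle 95% ran from −0.24 to 0.081. The list test had already set these genes apart, and the random lists were not matched on the position of the probes. The percentile therefore does not decide on such loss. RNA of leukocytes in the culture would bring their abundant transcripts along, but by limma 0 of 9 leukocyte markers were higher (0 at an unadjusted p under 0.05; fry adjusted p = 0.127), and PTPRC and CD74 read 11 and 23.3 in spheroids. A response of the fibroblasts to gathering or to storage may account for the rise, and it stays open and untested, since the control probe sets differ between the same groups.

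Mitosis genes stood lower in spheroids and in spheroid recovery than in monolayer. The same test of 5-prime signal loss put the list medians, −1.85 and −1.90, at percentiles 0 and 0 of random lists matched on mean level, whose middle 95% ran from −0.27 to 0.074 and from −0.46 to 0.12. The percentiles do not decide on such loss, since the random lists were not matched on the position of the probes. The list test had also already set these genes apart. An arrest of division in spheroids may account for the fall and was not tested, since RNA quality and group cannot be varied apart in these arrays.

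Between spheroid recovery and spheroids, 67 of 8252 genes (0.812%) had probe sets that changed at least 2-fold in opposite directions. Dim probe sets were taken to give fewer such genes among bright ones. With a mean of 100 or more on monolayer and monolayer recovery arrays the share was 1.83% (33 of 1801). At 100 or more in either compared group it was 2.5% (44 of 1762). Neither share decides on dim probe sets, since the offset of 16 keeps many of them from a 2-fold fall. A change can also carry a probe set past the second limit. Probe sets that can match other transcripts stay open, since the share was 0.762% (36 of 4723) with probe sets not named as matching several transcripts. Rising transcript forms outside the reference mRNA stay open too. In 16 such genes all rising probe sets came from 1 source, reference mRNA or other sequences, and all falling ones from the other source. The other sequences rose in 50% of these genes (8 of 16; exact binomial p = 1). Among all single-gene probe sets of known source changed at least 2-fold, 24.8% of rising and 31.8% of falling ones came from a reference mRNA. A share of 50% is therefore not a neutral mark. Partial breakdown of RNA, or a change in the use of transcript ends, may contribute, and neither was tested.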

How the results depend on the processing

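Scaling to the hybridization controls was the only alternative chosen only after the result was seen. With no detection calls, signal over background could not be assessed for dim probe sets, and 3 arrays per group limit the precision. A shared number in the sample names gave no pairing: r of residuals for 18 such pairs ran from −0.426 to 0.182, 5 of them over 0.1, and 3 of 12 arrays lay closest to an array of their own number. Unless a stricter threshold or fewer probe sets explains a change, the cause was not tested.

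With a 2-fold minimum the counts were 2119 for spheroid against monolayer, 5314 for spheroid recovery against monolayer, 22 for monolayer recovery against monolayer, 3556 for spheroid recovery against spheroid, 5881 for monolayer recovery against spheroid recovery and 5931 for any difference among groups. With 1 probe set per gene they were 6416, 9454, 923, 6911, 10244 and 10751, with fewer probe sets tested. Monolayer recovery against monolayer had 467 at an adjusted p under 0.01, 689 with an offset of 1, 2514 with array weights, and 701 to 1803 with 1 array left out. Probe sets changed the same way in spheroids and monolayer recovery numbered 165 with an offset of 1 and 164 to 379 with 1 array left out. Scaled to the hybridization controls, spheroid against monolayer had 38198 (1073 higher), spheroid recovery against monolayer 38103 (1975 higher), monolayer recovery against spheroid recovery 38103 (2026 lower), monolayer recovery against monolayer 1309 (832 higher, 477 lower) and spheroid recovery against spheroid 13555. Of 150 list tests 64 passed, and 22 did with an estimated correlation and 116 with fry.

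Directions of named genes and of list tests turned as follows. With quantile normalization TBP was at 0.123 in spheroid recovery against monolayer and −0.015 in monolayer recovery against spheroid recovery. Scaled to the hybridization controls, spheroid against monolayer had RRP12 at −0.095, SFN at −0.144, EDNRB at −0.319 and CIRBP at −0.411. Spheroid recovery against monolayer had KRT1 at −0.481, TYR at −0.437, GPR143 at −0.501, CDH5 at −0.334, PECAM1 at −0.354, ITGAM at −0.336, CIRBP at −0.004 and RBM3 at −0.569. Monolayer recovery against spheroid recovery had SFN at 0.299, KRT1 at 0.538, TYR at 0.423, PMEL at 0.447, PECAM1 at 0.094, CDH5 at 0.398, ROBO4 at 0.466, CD74 at 0.366, ITGAM at 0.455, CSF1R at 0.511, CIRBP at 0.025 and RBM3 at 0.487. By fry the direction was opposite to camera for fibroblast markers in spheroids (median 0.144), for apoptosis machinery (−0.012) and melanocyte markers (0.171) in spheroid recovery against monolayer, for hypoxia response in spheroid recovery against spheroid (−0.067), and for apoptosis machinery (0) and melanocyte markers (−0.199) in monolayer recovery against spheroid recovery. List medians turned under hybridization scaling in 43 of 150 cases, 15, 10, 3, 5 and 10 in the comparisons in the order given above, while no list test by camera turned. List calls were gained in 10 cases with that scaling, 7 with the mean over all probe sets, 5 with quantile normalization and 2 with a common median. Of 592 named values of genes, the number that lost the call without turning was 12 with quantile normalization (2 turned), 14 with a common median, 15 with no filter, 24 with an offset of 1, 22 with a replicate block, 50 at an adjusted p under 0.01, 172 with a 2-fold minimum, 16 with hybridization scaling (24 turned), and 4 to 34 with 1 array left out.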

Other observations

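The tests of an incomplete return from the spheroid state were chosen only after the result was seen. Several genes outside the lists fell steeply in spheroids. PTX3, a pattern recognition protein, fell from 1922 ± 127 in monolayer to 69.3 ± 9.61 in spheroids (mean ± SD, n = 3). ALDH1A1, which makes retinoic acid, fell from 2045 ± 40 to 82.3 ± 19.4 and stood at 23 ± 5.2 in spheroid recovery. DKK1, an inhibitor of Wnt signalling, fell from 1895 ± 72.7 to 78.7 ± 3.51. PSG5, a pregnancy-specific glycoprotein, had a log2 change of −4.96, and SSTR1 and OXTR, receptors of somatostatin and oxytocin, had changes of −4.27 and −3.81. In spheroid recovery EHD2, a protein of caveolae, fell from 1903 ± 91.7 to 38.7 ± 0.577. KBTBD8 and SLC25A34 rose in spheroid recovery against spheroids by 3.75 and 3.80, and TNFRSF11B, the decoy receptor osteoprotegerin, fell from 1864 ± 105 to 29.3 ± 2.31.

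The recovered monolayer differed from the starting one in genes outside the lists too. PTGIS, prostacyclin synthase, fell from 242 ± 20.8 to 57 ± 7.94, and COL15A1 from 435 ± 14.2 to 152 ± 27.6. EFEMP1 and ASPN, matrix proteins, fell by 1.20 and 1.14 on the log2 scale. BEX1 rose from 74 ± 9.54 to 252 ± 39.2, and TNFRSF21, a death receptor, rose by 1.14. Genes with opposite probe sets between spheroids and spheroid recovery included PPP4R3B and RECK, chosen after their values were seen. For PPP4R3B 1 probe set went from 260 ± 28.4 to 1182 ± 123 and another from 740 ± 43 to 31.7 ± 4.04.

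An incomplete return from the spheroid state would leave DNA replication and mitosis genes below their monolayer level in monolayer recovery, as they were in spheroids. The lower of the 2 list medians was 0.366, which is the opposite direction, but this restates the pattern and is no separate test of it. A candidate explanation is a difference in density or days since plating between the starting and the recovered monolayer, which the labels do not allow to be tested.

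Amino acid starvation response genes were lower both in spheroids and in monolayer recovery, for which an incomplete return may account. Across the 24 genes, which are not independent, the changes in spheroids and in monolayer recovery had Spearman's rho 0.323 (permutation p = 0.124) and Pearson's r 0.413. Shared monolayer arrays alone gave a simulated rho of 0.47 for genes without any change. These genes did change in spheroids, so that value is no measure for the observed rho, and the explanation stays open.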
